A study of Mus musculus with 9 samples.

How the data were processed

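Single-cell RNA was measured in 1 library of mouse cells from ascites, the fluid that gathers in the peritoneal cavity, of a model made with ID8-Def29/Vegf ovarian cancer cells. The values deposited by the authors for this library are counts of unique molecular identifiers (UMIs) per gene and barcode from a 10x Genomics assay. The deposited matrix had 27998 genes, 737280 barcodes and 35733776 UMIs, and no selection of cells had been applied to it. The aligner and genome build that the authors used are not given in the sources used here. A further 8 bulk libraries of cultured ID8-Def29/Vegf cells, 4 given vehicle and 4 given deferiprone for 12 h, are part of the series. The columns of their table, 8 in number, carry names that match no sample label, so no column could be placed in a group. The table was left out, and the planned edgeR comparison of deferiprone with vehicle was not run.

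Cells were kept with at least 500 UMIs, at least 200 genes and at most 15% of UMIs from mitochondrially encoded genes. Of the 6442 barcodes that passed, Scrublet (as implemented in scanpy 1.11.5) marked 89 (1.38%) as doublets, and 6353 cells remained. Symbols held by more than 1 gene (65 in all) were made unique. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen with the readout genes left out, so that no cluster was defined by them. Some natural killer cell markers used for naming, such as Ncr1 and Gzma, are readout genes. Genes were scaled with values limited to 10, and 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 with seed 1 gave 18 clusters. The other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

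Clusters were named "X-like" from marker genes of 21 cell types. The marker genes, the cell filter, the 5 lists of readout genes and 6 of the alternatives were chosen before the data were examined. The scoring rule for names was set while the clusters were being examined. It took the mean log2 ratio of a type's markers between a cluster and the cells outside its lineage, with 20 CPM added to each level. Lineages were clusters joined at a correlation distance of 0.15 over 500 variable genes, with 50 CPM added. A marker counted as detected at 50 CPM or more and at more than 2 times the level outside the lineage. A cluster with fewer than 3 detected markers stayed unnamed. The same held for a cluster whose median UMI count was under 1/3 of the library's when none of the name's markers was among its top 10 genes by fold.

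UMIs were summed over the cells of a class and given as CPM, the usual count rate, over all UMIs of that class, with an exact Poisson 95% interval. Shares of cells have an exact Clopper-Pearson 95% interval, and ratios between classes have an exact conditional binomial 95% interval. Intervals and limits cover counting error only. Since there was 1 library, no test was made between groups and no p-value is given. Free RNA in each class was estimated from markers of a cell type foreign to it, set against the profile of barcodes with 1 to 50 UMIs. A second estimate used barcodes with 100 to 200 UMIs and was added after the data had been seen. The first set held 306235 UMIs in 183846 barcodes and the second 7829300 UMIs in 58272 barcodes. Their profiles differed, with Malat1 at 44463 CPM in the first and 9861 in the second. The level that free RNA would give for a gene uses the first profile unless stated. The second can give another level, so a match to free RNA may depend on the profile. The limit that a count of 0 allows was taken as 3 counts. The depth of the library gave a median of 3300 UMIs and 1144.5 genes per barcode passing the cell filter, with a range of 500 to 19947 UMIs. The named genes were those of the readout lists with at least 50 UMIs over all kept cells, apart from 1 gene that is not reported here, and the 3 leading genes by fold of each cluster. Genes named outside this rule were chosen after their values were seen, except the natural killer cell markers and low-count readout genes, which belong to the fixed lists.

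Of the 26 gene lists prepared for the bulk libraries, 17 had at least 5 members measured well enough in the cells, and 9 had too few. For these 17, the median log2 ratio between the largest classes was ranked among those of 10000 random lists of the same size and matched expression. Genes used for clustering were left out, which left 3603 genes with a mean level of at least 20 CPM, and 5 CPM were added to each level. Readout genes, which could not be clustering genes, stayed in however variable they were. All members used of the iron list are readout genes. This use of the lists was chosen after the bulk table could not be used. Gene positions are from GENCODE release M21 on GRCm38, which held 27645 of the 27998 gene identifiers and lacked 353. Alternatives were stricter or looser cell filters, no removal of doublets, other clustering settings and subsets of cells. Clustering, naming, the free RNA estimate, ratio intervals and list ranking were tested on simulated data of 2500 cells in 6 classes. There 99.96% of cells were given their own class. The simulated classes came from barcodes rich in the naming markers, and their free RNA from the profile also used to estimate it. Recovery of both was therefore largely built in, and doublet removal was not part of the simulation. Simulated free RNA of 10% was estimated as 8.68% to 10.9%, and ratio intervals held the simulated value for 96% to 98% of 50 genes.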

Results

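The data describe the cells of ascites from mice that carried ID8-Def29/Vegf tumors, an ovarian cancer cell line changed to make a beta-defensin and the growth factor Vegf. They came from 1 library of 6353 kept cells, and the title of the series concerns iron chelation and innate immune control of metastatic ovarian cancer. The labels of this library name no treatment, so its values describe a single condition without replicates. Of the 35733776 UMIs in the library, 72.8% were in the 7435 barcodes with at least 500 UMIs.

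The comparison of cell classes addresses which cells the ascites held. Epithelial- or mesothelial-like cells, with Krt8, Krt18, Wt1 and Upk3b among their detected markers, made up 61.9% (60.7 to 63.1%, 3930 cells) of the kept cells. Epcam, Cdh1, Msln and Muc16, from the same marker list, were detected in none of their clusters. Macrophage-like cells, marked by the complement genes C1qa, C1qb and C1qc and by Csf1r, made up 19.7% (18.7 to 20.7%; 1250 cells). Conventional dendritic cell 2-like cells, led by the antigen presentation genes H2-Ab1, H2-Eb1 and Cd74, made up 6.44% (5.85 to 7.07%; 409 cells). For them 6 markers were detected, but their top 10 genes held none of these and 1 monocyte marker, Plac8. They also held all 10 UMIs of Xcr1 and all 23 of Itgae, markers of conventional dendritic cells 1, so their shares and levels may cover both types. B cell-like cells made up 2.99% (2.59 to 3.44%; 190 cells) and T cell-like cells 2.05% (1.71 to 2.43%; 130 cells). No cluster was natural killer cell-like.

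Smaller classes were fibroblast-like cells at 0.787% (0.585 to 1.04%), migratory dendritic cell-like cells at 0.630% (0.450 to 0.856%) and plasmacytoid dendritic cell-like cells at 0.346% (0.217 to 0.524%). Erythroid-like droplets, led by Hba-a1, Hba-a2 and Hbb-bs, made up 2.52% (2.15 to 2.93%). A cluster of 172 cells, 2.71% (2.32 to 3.14%), stayed unnamed. Among the 2041 leukocyte-like cells, 61.2% (59.1 to 63.4%) were macrophage-like, 20.04% (18.3 to 21.8%) conventional dendritic cell 2-like, 9.31% (8.08 to 10.7%) B cell-like and 6.37% (5.35 to 7.52%) T cell-like. The median depth ranged from 664 UMIs in B cell-like cells to 4797.5 in epithelial- or mesothelial-like cells.

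Within the epithelial- or mesothelial-like class, 8 clusters differed in their leading genes. The largest, of 975 cells, was led by Abcb1b, Lgals2 and C3, and the next, of 899 cells, by Gm26532, Gstm1 and Gstm2. A cluster of 789 cells was led by Pam, Abhd2 and Spry2, and a cluster of 344 cells by Abhd2, Defb19 and Pam. A cluster of 330 cells was led by Wfdc18, Gng13 and Sncg, and a cluster of 113 cells by Defb19, Defb36 and Actr3b. The 268 cells led by Top2a, Lockd and Birc5 carried genes of mitosis. The 212 cells led by mt-Cytb, mt-Nd1 and C3 had a median of 11.6% mitochondrial UMIs. Defb29, the defensin in the name of the implanted line, had UMIs in 3 of the 6353 cells.

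Macrophage-like cells fell into 2 clusters. The larger, of 841 cells, was led by Pf4, Saa3 and Wfdc17. The smaller, of 409 cells, was led by the neutrophil genes S100a9, S100a8 and Camp, with 4 macrophage markers and 2 neutrophil markers among its top 10 genes outside its lineage. The lead of S100a9 rested on few cells: at resolution 2, 8 neutrophil-like cells held it at 13541 CPM, and its macrophage-like level was 21.4 CPM in place of 235. B cell-like cells were led by Jchain, Cd79a and Ly6d, of which Jchain is a plasma cell marker; their top 10 genes held 2 B cell and 2 plasma cell markers. Ccl5, Nkg7 and Cd3d led T cell-like cells, and Ccl5, Ccr7 and AW112010 led migratory dendritic cell-like cells. Cox6a2, Bst2 and Siglech led plasmacytoid dendritic cell-like cells. Slpi, Mgp and Col1a2 led fibroblast-like cells, whose top 10 genes also held the mesothelial marker Msln. Some other epithelial or mesothelial markers were also higher in them than in the epithelial- or mesothelial-like class, such as Krt7 at 290.4 against 21.7 CPM and Upk1b at 229 against 39.7. The unnamed cluster was led by Emc2, Rps26-ps1 and Aasdhppt.

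**Figure D1:**
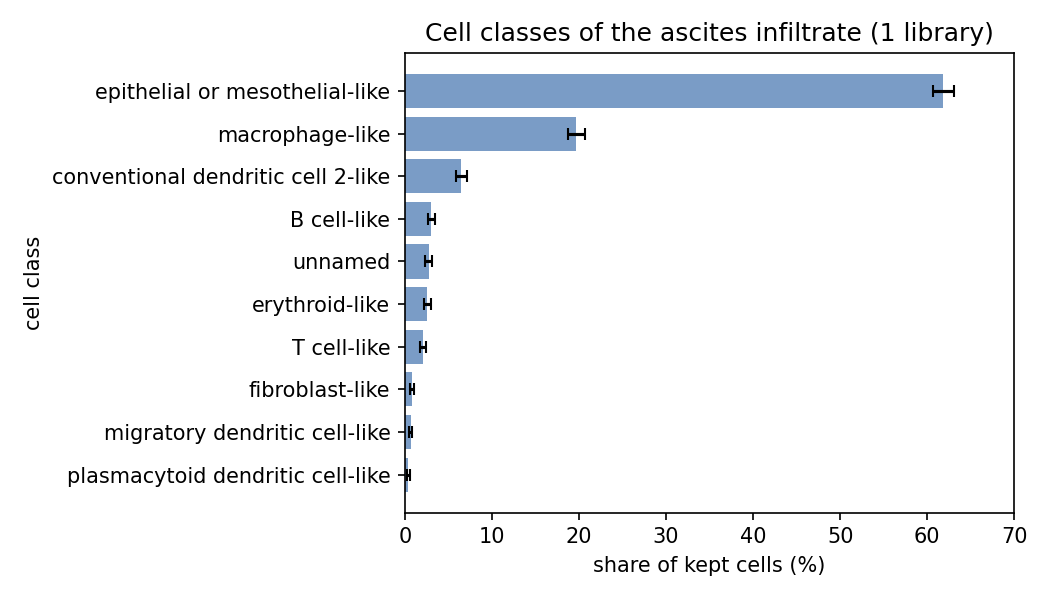
Share of the 6353 kept cells (percent, horizontal axis) in each cell class (vertical axis) of the 1 ascites library; bars are shares and error bars are exact 95% intervals for counting error. The epithelial- or mesothelial-like class held 61.9% and the macrophage-like class 19.7% of cells.

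Against barcodes of 1 to 50 UMIs, free RNA made up an estimated 4.05% of the UMIs of epithelial- or mesothelial-like cells, 10.9% in macrophage-like cells, 13.8% in conventional dendritic cell 2-like cells, 23.9% in T cell-like cells and 53.5% in B cell-like cells. It made up 6.31% in fibroblast-like, 17.0% in migratory dendritic cell-like and 31.1% in plasmacytoid dendritic cell-like cells. Against barcodes of 100 to 200 UMIs the estimates were 7.93% in epithelial- or mesothelial-like and 12.3% in fibroblast-like cells, 11.5% in macrophage-like, 14.6% in conventional dendritic cell 2-like, 25.3% in T cell-like and 56.6% in B cell-like cells. They were 18.0% in migratory and 32.9% in plasmacytoid dendritic cell-like cells. No estimate is given for erythroid-like droplets and the unnamed cluster, where epithelial markers may come from a captured cell. The same may hold for B cell-like cells, whose estimate was the highest of those given and may overstate free RNA. The erythroid-like share ranged from 0.291% to 7.41% over the alternatives. With at least 1000 UMIs per cell no B cell-like, T cell-like or plasmacytoid dendritic cell-like class was found. The unnamed share was then 1.17%, but those 65 cells were unlike the unnamed cluster of 172 cells, with S100a9 at 1761.5 against 0 CPM.

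Iron handling genes were compared between the largest classes, macrophage-like and epithelial- or mesothelial-like, since the title of the series concerns iron. Of the 21 genes in the list, 18 had enough UMIs: 8 were higher in macrophage-like cells, 4 were higher in epithelial- or mesothelial-like cells, and 6 had a ratio whose interval included 1. Directions here and below are read against a ratio of 1. The median log2 ratio of 3603 genes was 0.403 toward the epithelial- or mesothelial-like class. Fth1, the heavy subunit of the iron store ferritin, stood at 22862 CPM in macrophage-like cells and 6477 in epithelial- or mesothelial-like cells, 3.53-fold (3.49 to 3.57) higher. Ftl1, the light subunit, was 6.89-fold (6.80 to 6.97) higher. Hmox1, which breaks down heme and releases its iron, was 83.3-fold (76.4 to 91.0) higher, at 2329 against 28.0 CPM. Free RNA would give 7.68 of the 28.0 CPM.

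The scavenger receptor for haemoglobin-haptoglobin, Cd163, stood at 115 CPM in macrophage-like cells, and the phagosomal metal transporter Slc11a1 at 106 CPM. In epithelial- or mesothelial-like cells both were at 0.244 CPM, no higher than the 0.530 and 0.265 CPM that free RNA would give, so no fold of expression is given for them. Slc40a1, the iron exporter ferroportin, was 21.5-fold (13.2 to 36.0) higher, with all 56 macrophage-like UMIs in the cluster led by Pf4. Fbxl5, part of an iron-sensing ubiquitin ligase, was 4.51-fold (3.59 to 5.64) higher.

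Epithelial- or mesothelial-like cells had higher levels of Cp, the ferroxidase ceruloplasmin, by 6.86-fold (4.51 to 10.98), at 70.8 against 10.3 CPM. Tfrc, the receptor that takes up transferrin, was 2.36-fold (1.36 to 4.48) higher in them, at 14.4 against 6.10 CPM. The iron chaperone gene Pcbp2 was 2.04-fold (1.87 to 2.24) higher, and Slc25a28, a mitochondrial iron carrier, 1.80-fold (1.33 to 2.498) higher. Trf, which encodes transferrin, stood at 838 CPM in macrophage-like and 849 in epithelial- or mesothelial-like cells, a ratio of 0.987 (0.940 to 1.04). The ratios of Slc11a2, Slc39a14, Aco1, Ireb2 and Pcbp1 lay between 0.669 and 1.20, and their intervals included 1.

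Lcn2, which binds iron-carrying siderophores, was 2.51-fold (1.80 to 3.46) higher in macrophage-like cells, from 49 UMIs in that class. This direction turned under 4 alternatives, for example to 0.313-fold at resolution 2. There, 8 neutrophil-like cells formed a class of their own with 43 Lcn2 UMIs, and macrophage-like cells kept 6.

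**Figure D2:**
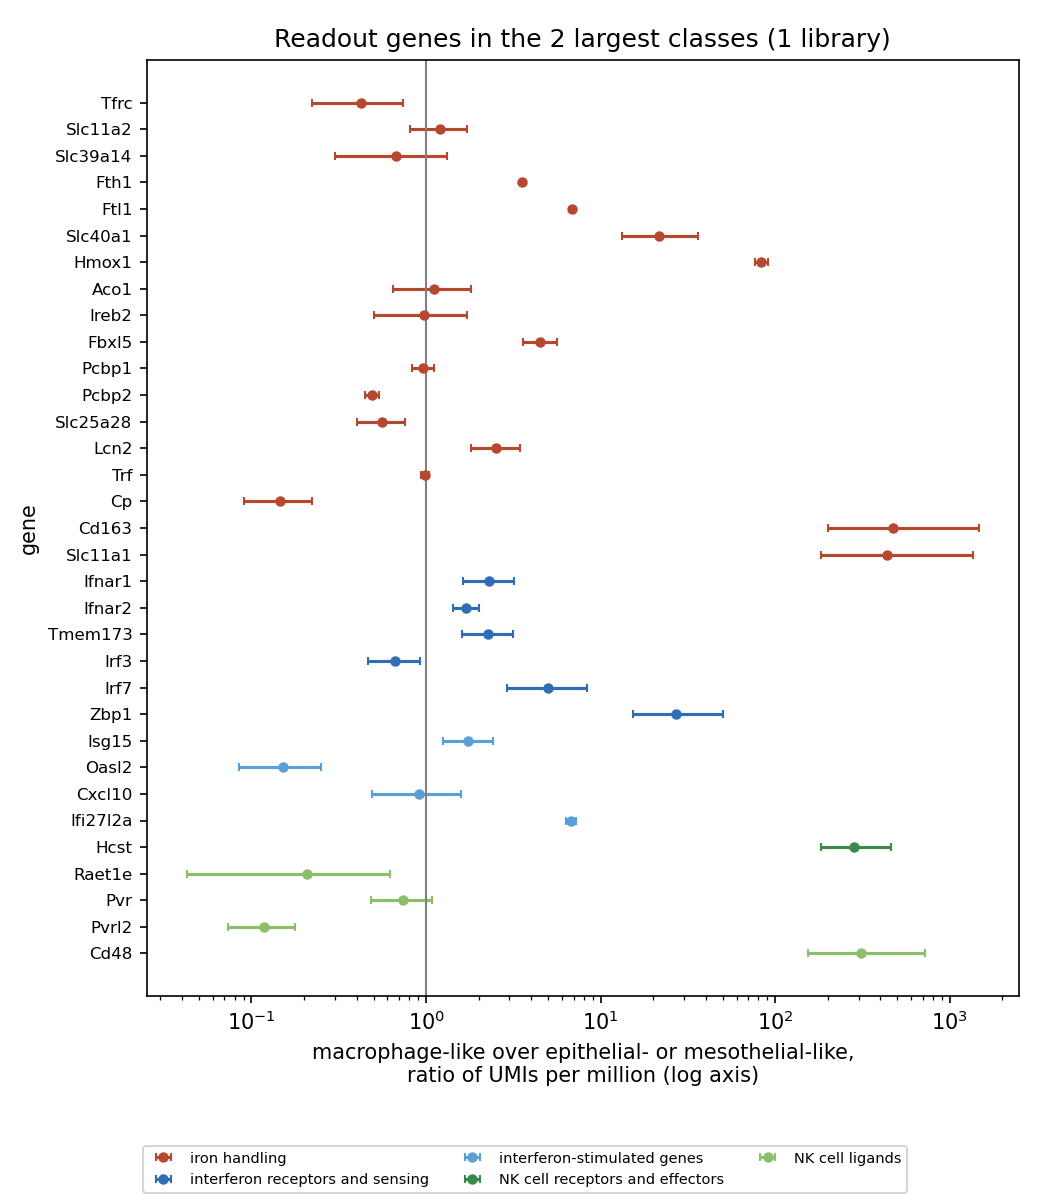
Ratio of CPM, macrophage-like over epithelial- or mesothelial-like class (horizontal log axis), for the readout genes reported here, each with at least 50 UMIs (vertical axis), coloured by list; points are ratios and error bars exact 95% intervals for counting error in 1 library. Hmox1 lies at 83.3 and Cp and Pvrl2 left of the line at 1, while the ratios of Cd163, Slc11a1, Hcst and Cd48 are taken against a level no higher than free RNA.

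The macrophage-like clusters differed in several iron genes. The cluster led by Pf4 had 2.87-fold (2.78 to 2.96) more Fth1 and 1.71-fold (1.66 to 1.75) more Ftl1 than the cluster led by S100a9. Its Hmox1 was 4.12-fold (3.69 to 4.62) higher, at 2829 against 686 CPM, and its Cd163 was 4.37-fold (2.63 to 7.77) higher. Slc11a1 was 2.56-fold (1.67 to 4.09) and Trf 1.69-fold (1.49 to 1.93) higher. Slc40a1 was at 34.2 CPM (25.9 to 44.5) in it and at 0 UMIs in the other, which allows up to 6.04 CPM. Fbxl5 had a ratio of 1.01 (0.653 to 1.62). Genes lower in the cluster led by Pf4 were Lcn2, at a ratio of 0.0424 (0.0148 to 0.1001) from 6 against 43 UMIs, as many as the 8 neutrophil-like cells held at resolution 2, Pcbp2 at 0.729 (0.602 to 0.886) and the interferon list gene Tmem173 at 0.456 (0.242 to 0.879).

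Other classes had lower ferritin levels than macrophage-like cells. Fth1 stood at 10594 CPM in fibroblast-like cells, 5557 in conventional dendritic cell 2-like cells and 3104 in T cell-like cells, where free RNA would give 476, 1042 and 1804. Ftl1 stood at 7014 CPM in migratory dendritic cell-like cells and 3649 in conventional dendritic cell 2-like cells. Hmox1 was at 23.1 CPM in conventional dendritic cell 2-like cells, where free RNA would give 26.1, and at 117 CPM in fibroblast-like cells.

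**Figure D3:**
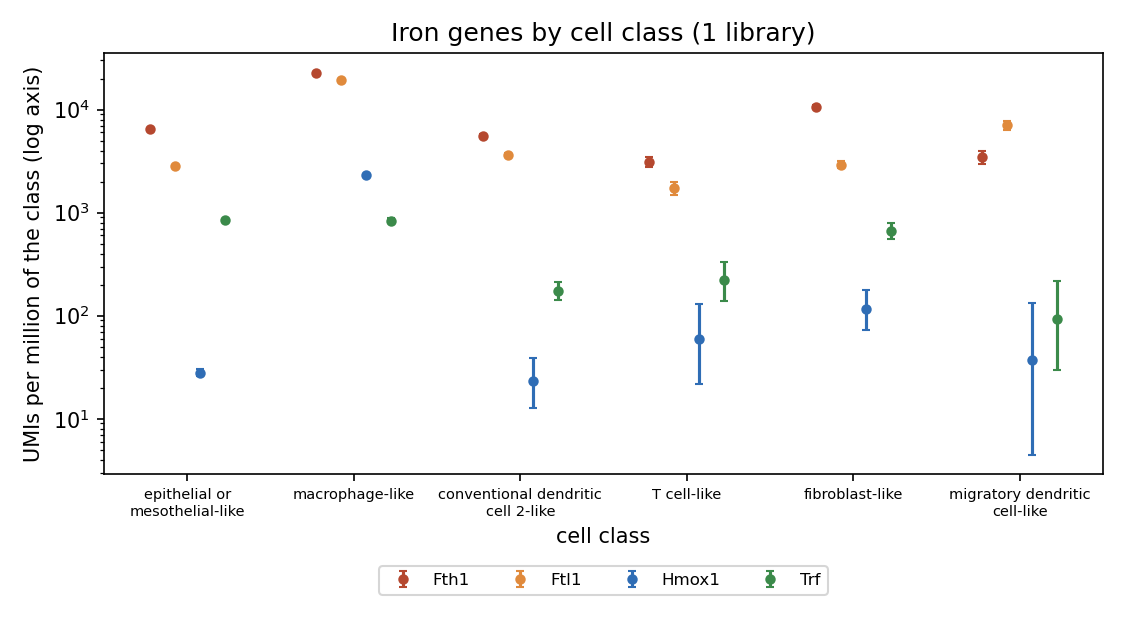
CPM of the class (vertical log axis) of Fth1, Ftl1, Hmox1 and Trf in 6 cell classes (horizontal axis) of the 1 ascites library; points are levels and error bars exact Poisson 95% intervals. Fth1 was at 22862 in macrophage-like and 6477 in epithelial- or mesothelial-like cells.

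Fth1 (ENSMUSG00000024661) lies on chromosome 19 from 9980598 to 9985098 of GRCm38, and Ftl1 (ENSMUSG00000050708) on chromosome 7 from 45457944 to 45459884. Hmox1 (ENSMUSG00000005413) lies on chromosome 8 from 75093621 to 75100589, and Tfrc (ENSMUSG00000022797) on chromosome 16 from 32608920 to 32632794. Cp (ENSMUSG00000003617) lies on chromosome 3 from 19957054 to 20009145, and Trf (ENSMUSG00000032554) on chromosome 9 from 103204001 to 103230444. These 6 genes are annotated as protein-coding. A pseudogene named after Ftl1 had 3399 UMIs over all barcodes, beside 135918 for Ftl1 itself.

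Interferon genes were compared between the same classes, since the series concerns innate immune control. Of the list of interferon receptors and sensing genes, 6 were counted, and 5 were higher in macrophage-like cells. Zbp1, a nucleic acid sensor, was 27.1-fold (15.3 to 50.3) higher and Irf7, a transcription factor of interferon genes, 5.01-fold (2.92 to 8.37). The interferon receptor genes Ifnar1 and Ifnar2 were 2.30-fold (1.63 to 3.19) and 1.69-fold (1.42 to 2.004) higher, and Tmem173, which encodes the sensor STING, 2.27-fold (1.60 to 3.16). Irf3 was 1.503-fold (1.08 to 2.15) higher in epithelial- or mesothelial-like cells. With 5 CPM added its log2 ratio was 0.478, near the median of 0.403 over 3603 genes.

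Interferon-stimulated genes went in both directions. Ifi27l2a was 6.78-fold (6.35 to 7.24) higher in macrophage-like cells, at 715 against 105 CPM, and Isg15 was 1.75-fold (1.24 to 2.41) higher. Oasl2 was 6.61-fold (3.99 to 11.9) higher in epithelial- or mesothelial-like cells. Cxcl10 had a ratio of 0.914 (0.488 to 1.58). Oasl2 reached 195 CPM in fibroblast-like cells, from 35 UMIs. Several others were at low counts, such as Ifit2 with 36 UMIs and Rsad2 with 23, and Ifit1 had UMIs in 8 of the 6353 cells. Without removal of doublets the macrophage-like over epithelial- or mesothelial-like ratio of Oasl2 was 0.284, against 0.151 with removal.

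Natural killer cell genes were compared to see which cells carry the receptors and their ligands. Hcst, which encodes an adaptor of the activating receptor Klrk1, stood at 868 CPM in T cell-like and 290.7 CPM in macrophage-like cells. In epithelial- or mesothelial-like cells it was at 1.03 CPM, where free RNA would give 1.72. It was the sole gene of the 11 receptor and effector genes with at least 50 UMIs. Among ligand genes, Pvrl2, whose product binds the receptor Cd226, was 8.53-fold (5.62 to 13.6) higher in epithelial- or mesothelial-like cells, at 88.0 against 10.3 CPM, of which free RNA would give 5.67. Raet1e, a ligand of Klrk1, was 4.79-fold (1.61 to 23.5) higher in them, from 138 against 3 UMIs. The macrophage-like level of Raet1e had an interval of 0.2901 to 4.11 CPM, which includes the 0.709 CPM of free RNA. Cd48 stood at 120.5 CPM in macrophage-like cells and at 0.391 CPM in epithelial- or mesothelial-like cells, where free RNA would give 0.397, and Pvr had a ratio of 0.736 (0.486 to 1.07). Without removal of doublets the macrophage-like over epithelial- or mesothelial-like ratio was 0.187 for Pvrl2 and 0.365 for Raet1e, against 0.117 and 0.209 with removal. With at most 25% mitochondrial UMIs that of Raet1e was 0.354.

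Markers of natural killer cells were rare. Ncr1, Eomes, Gzmb and Klrc1 had 0 UMIs in 6353 cells, which allows a share of cells with a UMI of up to 0.0472%. Klrb1c had a UMI in 1 cell, Klra8 in 2, Gzma in 3, Klre1 in 6 and Prf1 in 1, while Ifng, which encodes interferon gamma, had UMIs in 2 cells. The UMIs of Klrb1c and Klra8 and 3 of the 4 of Gzma were in T cell-like cells, and 3 cells held 2 of the markers other than Klre1, Klrk1 and Klrd1. Klrk1 had UMIs in 44 cells and Klrd1 in 119 cells, with 26 of 46 and 128 of 148 UMIs in conventional dendritic cell 2-like cells. Natural killer cells were not detectable as a class at this depth and with the receptor and effector readout genes left out of the clustering.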

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

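All tests in this part were chosen after the result was seen. In the 474 barcodes excluded for having fewer than 200 genes, haemoglobin genes made up 83.4% (83.3 to 83.5%) of 487916 UMIs, a signal in data that the comparisons of cell classes did not use. In 471 of these barcodes haemoglobin took more than 50% of the UMIs. The barcodes that passed the cell filter had 0.494% haemoglobin UMIs.

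Macrophage-like cells held 8385 haemoglobin UMIs, of which 6767 were in 19 cells with 20 or more each, while free RNA of lysed red cells would give 0.0031 such cells and is excluded as the whole cause. In the other macrophage-like cells, where haemoglobin was at 0.542 (0.516 to 0.569) of the level that free RNA would give, or 0.883 with barcodes of 100 to 200 UMIs, free RNA may account for it, although the lower bound lay just above the limit of 0.5 set for that. Chance capture of a red cell beside another cell stays open: 43.2% of 125 droplets with 20 or more haemoglobin UMIs had more macrophage than epithelial UMIs, against 28.0% of 6174 others, but 95 of the 125 were erythroid-like, and there free RNA and a second cell cannot be told apart. Outside the erythroid-like class, 19 of 1250 macrophage-like, 7 of 3930 epithelial- or mesothelial-like and 1 of 40 migratory dendritic cell-like cells reached 20 haemoglobin UMIs. So did 1 of 409 conventional dendritic cell 2-like, 1 of 190 B cell-like, 1 of 130 T cell-like and 2 of 172 unnamed cells. No fibroblast-like or plasmacytoid dendritic cell-like cell did. Pairs named erythroid-like or removed as doublets are missing from these counts. Red cells attached to or taken up by macrophages also remain open, and no biological explanation was tested.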

How the results depend on the processing

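No paired analysis was possible because a single library was used. The alternatives intended for deferiprone against vehicle, including leaving out each library in turn, were not run. The alternatives with at least 100 genes per cell, without Xist in the clustering, without cells of 20 or more haemoglobin UMIs and without the clusters of low quality were chosen after seeing the data. Of the class shares and the ratios of Fth1, Ftl1, Hmox1, Trf and Tfrc, 118 values stayed within the interval of the reported value and 27 moved outside it. Of the ratios of other genes, 282 stayed within, 4 moved and 4 turned direction.

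The epithelial- or mesothelial-like share was 70.1% with at least 1000 UMIs, 64.3% with at most 25% mitochondrial UMIs, 58.1% with at least 100 genes and 63.5% without haemoglobin-rich cells. The macrophage-like share was 18.0%, 18.5% and 18.7% under the first 3 of these and 20.9% without low-quality clusters. The conventional dendritic cell 2-like share was 5.22% with at least 1000 UMIs, 5.23% without removal of doublets, 4.75% at resolution 2 and 4.72% with 3000 variable genes; in each, a conventional dendritic cell 1-like class of 99 to 113 cells appeared. The unnamed share was 1.17% with at least 1000 UMIs, in cells unlike the reported unnamed cluster, and 3.26% with at least 100 genes. The erythroid-like share was 1.92% with at most 25% mitochondrial UMIs, 5.05% at resolution 0.5, 1.94% with 3000 variable genes, 7.41% with at least 100 genes and 0.291% without haemoglobin-rich cells.

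With at least 1000 UMIs the ratio of Fth1 was 3.68, that of Ftl1 7.03 and that of Trf 1.04. Without removal of doublets Fth1 was 3.30 and Ftl1 6.33, and at resolution 2 they were 3.58 and 6.98. Fth1 was 3.49 with at least 100 genes. Lcn2 turned to 0.332 with at least 1000 UMIs, 0.361 without removal of doublets, 0.313 at resolution 2 and 0.726 with 3000 variable genes. Under these, in turn, macrophage-like cells had 6, 8, 6 and 14 of the UMIs of Lcn2, against 49, and 35 were in unnamed, 43 in T cell-like, 43 in neutrophil-like and 35 in T cell-like cells, where in the reported setting unnamed cells had 4 and T cell-like cells 0. For the other values the cause was not tested. Depth limits the small classes: with at least 1000 UMIs no B cell-like, T cell-like or plasmacytoid dendritic cell-like class gave a value. No unnamed cluster existed at resolution 0.5 or without the low-quality clusters.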

Other observations

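The tests in this part were chosen after the result was seen, except those of X-linked genes and of Tfrc in macrophage-like cells. Gene lists prepared for the bulk libraries showed how epithelial- or mesothelial-like cells differed from macrophage-like cells beyond iron. The 3603 genes compared had a median log2 ratio of 0.40, epithelial- or mesothelial-like over macrophage-like. Extracellular matrix genes (median 2.93, percentile 100 among random lists) were higher in the epithelial- or mesothelial-like class. Epithelial and mesothelial genes (3.17, percentile 100) tell nothing more, since all 6 members used are markers that named the class. Sparc, a matrix glycoprotein gene, stood at 1123 CPM against 83.0 in macrophage-like cells, where free RNA would give 80.1. Sparc was at 738 CPM in barcodes of 1 to 50 UMIs and 471 in those of 100 to 200, so the second profile would give less. Mitochondrially encoded transcripts had a median of 1.15 (percentile 99.5; 10 of 10 higher), such as mt-Co1 at 9917 against 4628 CPM. DNA replication genes had a median of 1.0 (percentile 96.4; 8 of 11 higher), with Rrm1 at 56.6 against 13.6, and ribosome biogenesis genes 0.85 (percentile 95.7; 15 of 16 higher), with Myc at 48.6 against 15.9.

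Genes of other stress and metabolic lists stood lower than the rest in the epithelial- or mesothelial-like class. NRF2 and glutathione antioxidant genes had a median of -0.43 (percentile 0.060, 5 of 17 higher), although Acsl4 went the other way at 103.5 against 19.7 CPM. This list also holds the readout genes Fth1, Ftl1 and Hmox1, so its median and rank rest in part on iron genes that were exempt from the removal of clustering genes. Endoplasmic reticulum chaperones had a median of -0.46 (percentile 0.090; 3 of 14 higher), with Pdia6 at 43.8 against 91.0, and glycolysis genes -0.50 (percentile 0.25; 2 of 11 higher), with Pkm at 199.5 against 505.5. MHC class I presentation genes had a median of -0.46 (percentile 2.03, 1 of 7 higher). The members used did not include H2-K1, H2-D1 or B2m, and Calr and Canx among them are also in the endoplasmic reticulum list. The remaining lists lay between percentiles 14.2 and 83.4: iron uptake, storage and export at 0.02 (14.2), mitophagy at 0.16 (18.5), HIF targets at 0.31 (36.4), ATF4 response at 0.30 (38.4) and the respiratory chain at 0.30 (47.6). The others were p53 targets at 0.48 (60.2), iron-sulfur cluster and heme synthesis at 0.58 (70.7) and chromatin dioxygenases at 0.81 (83.4).

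Xist, the RNA that silences an X chromosome in female cells, was nearly absent from epithelial- or mesothelial-like cells. Its level in them was 1.37 CPM (0.909 to 1.98), where free RNA would give 1.19. Xist was at 29.4 CPM in barcodes of 1 to 50 UMIs and 6.0 in those of 100 to 200. The second profile would give a level below that interval, so free RNA may not account for all of the 1.37 CPM. Xist stood at 273.9 CPM in macrophage-like cells, 271 in B cell-like cells, 236 in conventional dendritic cell 2-like cells and 218 (155 to 298) in fibroblast-like cells. Too few UMIs are excluded as the cause, since the macrophage-like level would give 5604 UMIs and 28 were seen, and so is sorting by the clustering, since the level was 1.32 CPM without Xist in the clustering. In the ratio to macrophage-like cells, X-linked genes were lower than autosomal genes by a log2 difference of -0.15 (-0.39 to -0.03, 88 X-linked genes). This argues against an X chromosome pair without silencing. The interval covers the choice of genes only, not differences between cell types in X-linked expression. Origin from an implanted line that has lost an X chromosome, beside host cells, may be a candidate explanation, but genotypes were not analysed here and this origin was not tested.

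The unnamed cluster of 172 cells had 11356 Malat1 CPM, near the 9861 of barcodes with 100 to 200 UMIs and far from the 70953 of the epithelial- or mesothelial-like class. Malat1 is a nuclear RNA. Mitochondrial UMIs were 0.989% of its UMIs, beside 0.644% in those barcodes. Barcodes with 1 to 50 UMIs were unlike the cluster, at 44463 CPM of Malat1 and 4.06% mitochondrial UMIs. Malat1, mitochondrial UMIs and epithelial markers (1542 against 1540 CPM) were thus near their levels in barcodes of 100 to 200 UMIs. Tyrobp, at 43.0 CPM (18.6 to 84.7) against 265, and Hbb-bs, at 1123 (976 to 1286) against 3962, were lower. Droplets filled only with free RNA of that kind therefore do not account for all these values, and no biological explanation was tested.

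The mitotic cluster of epithelial- or mesothelial-like cells had 2.0-fold (1.44 to 2.72) more Tfrc than the other clusters of the class, at 26.3 against 13.1 CPM, while Cp (0.609-fold, 0.483 to 0.758) and Oasl2 (0.519-fold, 0.380 to 0.694) were lower in it. The hypothesis that Tfrc is higher in dividing cells in general was tested in macrophage-like cells. The 48 cells with 2 or more UMIs of 34 mitosis genes had 10.6-fold (2.72 to 36.7) more Tfrc than the others, from 5 against 8 UMIs, which is consistent with it. The others stood at 3.97 CPM, not shown to be above the 2.48 CPM of free RNA, so the size of this fold is uncertain. Tfrc was at 22.9 CPM in barcodes of 1 to 50 UMIs and 8.17 in those of 100 to 200, so the second profile would give less free RNA. Epithelial markers, examined afterwards, stood at 244 CPM in those 48 cells and 253 in the others, which argues against droplets shared with an epithelial-like cell. The counts are few, and Tfrc and mitosis genes were read in the same cells of 1 library.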
